A study of Mus musculus with 20 samples.

How the data were processed

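Total RNA from 20 subcutaneous MMC tumours, stored in RNAlater and purified with the RNeasy kit, was hybridized to nCounter probes, per the labels' protocols. Each mouse carried the MMTV-Erbb2 transgene on the FVB/N background and was assigned to its group by tumour size, per the labels' protocols. Antibody or conjugate was given intraperitoneally at 5 mg/kg, and tumours were taken on day 1, per the labels. Groups were taken from the treatment label, with 5 tumours in each of 4 groups.

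The deposited values are a normalized signal for 770 genes in each tumour, on a linear scale, and the labels do not state how the authors normalized them. The normalization software, cartridge or run of each tumour, treatment of background and use of control probes are not given in the sources used here, so no batch was tested. From the values themselves, 100% of values above 1 and up to 1000 in every tumour were whole multiples of 1 step per tumour, within 0.02 of a count. The step, the signal of 1 count, lay between 0.826 and 1.33. No value was below 1, and 344 stood at 1. Where the step was above 1, a value of 1 count stood above 1 and is not among these 344. The geometric mean of 20 reference genes, all members of the list fixed below except Tfrc, was between 389.26 and 389.27 in all tumours, as a scaling on these genes would give, although no label names such a step. Dividing by the step gave back whole counts, 271793 to 508433 per tumour. A check of the lowest values alone found the step in 15 of the 20 tumours, and in the other 5 it rests on the wider range of values. No pair of tumours had identical values, and within groups the counts of any pair differed by a chi-square of at least 4.59 per degree of freedom, so all 20 were kept as separate samples.

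Signals were tested as log2(signal + 1) with limma 3.58.1 in R 4.3.3. A single fit over all 20 tumours with a mean per group was followed by eBayes without a trend. The 6 comparisons began with the anti-rHER2 ISAC against the isotype antibody, against anti-rHER2 and against the isotype ISAC, in this order. Next came anti-rHER2 against the isotype antibody, the isotype ISAC against the isotype antibody, and the interaction of target and T785. The p values are 2-sided and adjusted by Benjamini-Hochberg over the 770 genes of a comparison, and a gene was called at an adjusted p below 0.05. No gene was filtered out. Fold changes are on the log2(signal + 1) scale and understate changes of genes near the floor, whose signals rest on a few counts. Symbols were checked against the RefSeq annotation of GRCm38.p6, where 764 of 770 matched a symbol or synonym and 754 were current symbols, and 1 pair of symbols stood for the same gene. Symbols are printed as deposited. Probe sequences and positions are not given in the sources used here, so no coordinates are printed.

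The design, the alternatives, the rule for named genes and 25 gene lists, with 4 to 29 measured members, were fixed before the data were examined. Named genes were the 12 highest and 8 lowest log2 fold changes among called genes in each comparison of the anti-rHER2 ISAC, and the 5 highest and 5 lowest in each other comparison, leaving out reference genes. To these were added up to 4 members of each list with the largest change, and 16 genes fixed for every comparison (Erbb2, Tlr7, Tlr8, Fcgr1, Fcgr3, Fcgr4, Cd40, Cd86, Ifnb1, Tnf, Il12b, Cxcl9, Cxcl10, Ccl2, Cd8a and Ncr1). Some genes the rule allows are not reported here and are left out of the counts of named genes. Lists were tested with fry, adjusted over the 25 lists of a comparison, and with camera with the correlation between genes estimated from the data. The fry test asks whether members move one way on balance, and camera compares a list with the other genes of the panel. The members called were counted over all genes and adjusted over the list alone.

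Alternatives set before the data were examined were equal means of the fixed list of reference genes, equal medians of all genes, quantile normalization, leaving out the 192 genes of lowest mean, a pseudocount of 10, only the compared groups in the fit, a replicate block, array weights, a trended robust prior, an absolute log2 fold change of at least 1, an unmoderated 2-group test with unequal variances, camera, and leaving out each tumour in turn. After the data were seen, edgeR 4.0.16 (quasi-likelihood test on the recovered whole counts, keeping the deposited scaling) and scaling by the median of each tumour's log2 ratios to the gene means were added. By edgeR 350, 187, 311, 80, 0 and 62 genes were called in the 6 comparisons, in the order above.

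The limma, edgeR, fry and camera tests were tried on simulated data before use, with 770 genes and known changes. The other scalings, thinning, splits of the tumours, left-out tumours, array weights, the replicate block and the rule for tumours that stand apart were not simulated. For the anti-rHER2 ISAC against the isotype antibody, limma recovered 40.3%, 79.1% and 97.0% of genes changed 1.5-fold, 2-fold and 4-fold, with 3 false calls, and edgeR 41.8%, 77.6% and 97.0%. For the interaction limma recovered 22.4%, 59.7% and 89.4%. With no gene changed, limma made 0 calls for the isotype ISAC against the isotype antibody. Of 10 sets with 8 of 15 genes raised, fry called 10 and camera 9, and neither called a set with no changed gene. The simulated genes varied independently, with as many raised as lowered. These rates therefore do not carry over to lists of correlated genes or to a shift of the whole panel. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.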

Results

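Gene expression was measured in 20 subcutaneous MMC tumours, each from a different mouse, on day 1 after an intraperitoneal dose of 5 mg/kg. MMC is a mouse mammary carcinoma line, grown here in mice that carry an Erbb2 transgene under the MMTV promoter, and anti-rHER2 is an antibody against rat HER2. The 4 groups of 5 tumours received an isotype control antibody, an isotype antibody conjugated to T785, anti-rHER2, or anti-rHER2 conjugated to T785. The conjugates are immune-stimulating antibody conjugates (ISACs), and T785 is an agonist of the endosomal RNA sensors TLR7 and TLR8. An nCounter panel gave a normalized signal for 770 mouse genes, which is a count of probe molecules multiplied by a factor per tumour. Recovered totals were 271793 to 395944 counts per tumour with the isotype antibody, 320787 to 431518 with the isotype ISAC, 297116 to 432499 with anti-rHER2 and 398311 to 508433 with the anti-rHER2 ISAC. Lcn2, which encodes lipocalin-2, took 22.9% to 33.5% of the counts. The median signal of all genes was 56.4 ± 5.68, 56.3 ± 5.10, 68.8 ± 5.60 and 93.5 ± 11.6 in these groups. Signals below are mean ± SD over 5 tumours, and fold changes are differences on the log2(signal + 1) scale with their standard error, which understate the change of genes near the floor of 1.

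The anti-rHER2 ISAC was set against the isotype antibody to ask what antibody and payload did together. S100a8, which encodes a calprotectin subunit abundant in neutrophils, was 1225 ± 442 in the anti-rHER2 ISAC tumours and 30.4 ± 8.43 in the isotype antibody tumours, a log2 fold change of 5.24 ± 0.30 (limma adjusted p = 4.2e-10). Cxcr2, a neutrophil chemokine receptor gene, rose from 3.74 ± 2.4 to 113 ± 35.1, and the chemokine gene Ccl5 from 45.1 ± 17.9 to 723 ± 300.4. Among the next highest fold changes were those of Chil3 (3.98 ± 0.73), Ccl4 (3.86 ± 0.32), Fpr2 (3.56 ± 0.27), Ccl3 (3.52 ± 0.41), Ifitm1 (2.92 ± 0.26), Cxcl13 (2.77 ± 0.41), Slc11a1 (2.70 ± 0.20) and Csf3r (2.67 ± 0.27), and each of these 11 genes was higher in 5 of 5 treated tumours than in every control tumour. The lowest fold changes among genes that passed were those of Ccl17 (-1.57 ± 0.43), Tnfsf18 (-1.55 ± 0.32), H2-Ab1 (-1.25 ± 0.21), Cxcl15 (-1.19 ± 0.25), Clec4n (-1.14 ± 0.21), Cxcl1 (-1.12 ± 0.22), Cd83 (-1.03 ± 0.24) and Ccl1 (-0.85 ± 0.26). Ccl17 was close to the floor, at 3.16 ± 1.66 against 11.2 ± 4.67, whereas H2-Ab1, an MHC class II gene, fell from 2417 ± 585 to 1006 ± 212.

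**Figure D1:**
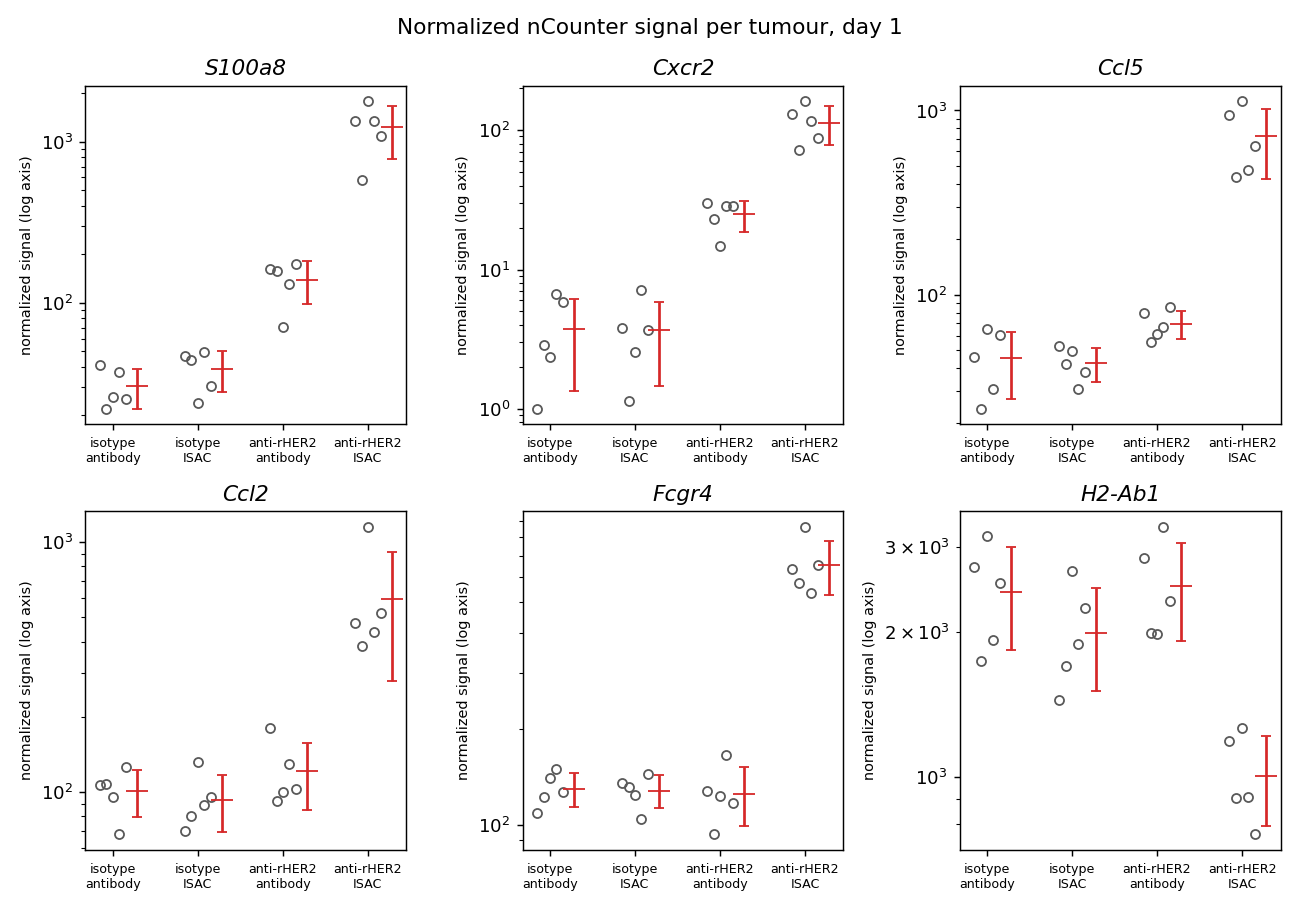
Normalized nCounter signal of 6 genes in each of the 20 tumours by treatment group, on a logarithmic axis, with open circles for single tumours and red marks for the group mean and SD (n = 5). Fcgr4 averaged 653 with the anti-rHER2 ISAC against 129.9, 128 and 125 with the isotype antibody, the isotype ISAC and anti-rHER2, and H2-Ab1 averaged 1006 against 2417, 1990.3 and 2486.

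Across the 770 genes, 307 were higher and 36 lower (limma, adjusted p below 0.05), and the median log2 fold change was 0.36, so each fold change of this comparison stands against a shift of that size. Higher and lower calls numbered 159 and 141 with median-ratio scaling, 130 and 182 with quantile normalization and 93 and 301 with equal medians, where the median of all genes was -0.027, -0.095 and -0.36. Of the 343 calls, 195, 165 and 129 were made there in the same direction and 4 in the opposite direction with quantile normalization and 32 with equal medians. Of the 68 named genes called, 49 kept the call and direction under these 3 scalings and under equal means of the fixed reference list, the exceptions being Erbb2, Il12b, Cxcl10, Ifit3, Ptgs2, Icos, Lck, Cd27, Nlrc5, H2-D1, Fn1, Col1a1, Muc1, Sap130, Sdha, Gusb, Il2ra, Eng and Ccr3. Named genes, here and below, were chosen mainly for large fold changes as deposited, so they keep calls more readily than called genes at large. Equal means of the reference list come close to the deposited scaling, as 20 of its genes were already level, and kept all 307 higher calls. With median-ratio scaling, quantile normalization and equal medians 12, 6 and 5 of the 23 list calls below were made in the same direction, and 2, 2 and 7 in the opposite direction.

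Of the genes for Fc-gamma receptors and antibody effector functions, 9 of 10 were higher and 0 lower (10 and 0 adjusted over the list alone), with a median of 1.40. The Fc-gamma and effector list had a fry adjusted p of 1.2e-08 and a camera adjusted p = 0.266 with an estimated correlation. For every list below, the value with an estimated correlation is likewise that of camera. Camera sets a list against the other genes of the panel, whose median rose by 0.36 here, and so asks another question than fry. A high camera value does not say that fry's shift is absent. Among its members Fcgr4, an activating IgG receptor, rose by 2.31 ± 0.15, its signalling chain Fcer1g by 2.00 ± 0.14 and Fcgr1 by 1.51 ± 0.19, while Fcgr3 was at 0.50 ± 0.21 (limma adjusted p = 0.0576) and was called higher with equal means of the reference list. Of the monocyte-recruiting chemokine genes, 9 of 14 were higher and 0 lower (10 and 0 adjusted over the list alone), with a median of 1.48. The monocyte-recruiting chemokine list had a fry adjusted p of 1.3e-06 and adjusted p = 0.629 with an estimated correlation. Ccl2 was at 2.45 ± 0.27. Of the neutrophil genes, 7 of 17 were higher and 1 lower (7 and 1 adjusted over the list alone), with a median of 0.57. The neutrophil list had a fry adjusted p of 1.3e-06 and adjusted p = 0.762 with an estimated correlation. Of the monocyte and macrophage markers, 11 of 17 were higher and 0 lower (12 and 0 adjusted over the list alone), with a median of 0.73. The monocyte and macrophage list had a fry adjusted p of 4.4e-06 and adjusted p = 0.762 with an estimated correlation. Itgam was at 2.64 ± 0.18 and Msr1 at 2.11 ± 0.17. Of the inflammatory cytokine genes, 7 of 18 were higher and 0 lower (7 and 0 adjusted over the list alone), with a median of 0.44, and the direction of the test turned with equal medians. The inflammatory cytokine list had a fry adjusted p of 1.3e-06 and adjusted p = 0.762 with an estimated correlation. The interleukin-1 antagonist gene Il1rn rose by 2.45 ± 0.18, Il10 by 2.18 ± 0.33 and Osm by 1.91 ± 0.37, Ptgs2 was at 1.82 ± 0.49 and Il12b at 0.88 ± 0.33, and Tnf (0.42 ± 0.35, limma adjusted p = 0.361) did not pass. Of the NF-kB and TLR genes, 15 of 29 were higher and 0 lower (16 and 1 adjusted over the list alone), with a median of 0.45, and the direction of the test turned with equal medians and quantile normalization. The NF-kB and TLR list had a fry adjusted p of 1.5e-06 and adjusted p = 0.762 with an estimated correlation. Tlr8 was at 1.64 ± 0.17 and Tlr9 at 1.42 ± 0.28. Tlr7 was 28.7 ± 8.15 against 22.5 ± 8.62 (limma adjusted p = 0.278). Of the complement genes, 10 of 25 were higher and 0 lower (10 and 0 adjusted over the list alone), with a median of 0.59. The complement list had a fry adjusted p of 7.3e-05 and adjusted p = 0.762 with an estimated correlation. Among anaphylatoxin receptor genes C5ar1 was at 2.06 ± 0.23 and C3ar1 at 2.00 ± 0.16.

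Of the type I interferon response genes, 18 of 28 were higher and 0 lower (18 and 0 adjusted over the list alone), with a median of 0.70, and the direction of the test turned with equal medians. The type I interferon list had a fry adjusted p of 0.000629 and adjusted p = 0.762 with an estimated correlation. Oasl1 was at 1.64 ± 0.23, Irf7 at 1.33 ± 0.26 and Ifit3 at 1.31 ± 0.31. Ifnb1 itself was close to the floor, at 1.87 ± 0.992 against 2.49 ± 0.982 (limma adjusted p = 0.529), and was called lower with equal medians. Of the interferon-gamma response genes, 10 of 19 were higher and 1 lower (11 and 1 adjusted over the list alone), with a median of 0.89, and the direction of the test turned with equal medians. The interferon-gamma list had a fry adjusted p of 0.00185 and adjusted p = 0.762 with an estimated correlation. Cxcl9 was at 2.49 ± 0.38, Gbp5 at 1.46 ± 0.32 and Cxcl10 at 0.94 ± 0.31. Cd274, which encodes PD-L1, rose by 2.32 ± 0.30. Of the MHC class I genes, 9 of 15 were higher and 1 lower (11 and 1 adjusted over the list alone), with a median of 0.78, and the direction of the test turned with equal medians. The MHC class I list had a fry adjusted p of 0.00171 and adjusted p = 0.762 with an estimated correlation. H2-D1 was at 0.87 ± 0.20, and their regulator Nlrc5 at 1.08 ± 0.25. Of the MHC class II genes, 1 of 11 was higher and 4 lower (1 and 4 adjusted over the list alone), with a median of -0.40. The MHC class II list had a fry adjusted p of 0.192 and adjusted p = 0.537 with an estimated correlation. H2-Aa was at -0.72 ± 0.23. Dendritic cell markers went both ways, as Clec4a2 (2.17 ± 0.19), Itgax (1.44 ± 0.17) and Ccr7 (1.82 ± 0.30) rose while Ccl17 and Cd83 fell: 3 of 14 were higher and 2 lower (3 and 2 adjusted over the list alone), with a median of 0.094, and the direction of the test turned with equal medians and quantile normalization. The dendritic cell list had a fry adjusted p of 0.0295 and adjusted p = 0.762 with an estimated correlation. Of the co-stimulation genes, 6 of 17 were higher and 1 lower (6 and 1 adjusted over the list alone), with a median of 0.42, and the direction of the test turned with equal medians and quantile normalization. The co-stimulation list had a fry adjusted p of 0.026 and adjusted p = 0.762 with an estimated correlation. Slamf7 was at 1.31 ± 0.21. Neither Cd40 (0.41 ± 0.24, adjusted p = 0.173) nor Cd86 (-0.099 ± 0.21, adjusted p = 0.713) passed limma as deposited, and Cd86 was called lower with median-ratio scaling, quantile normalization and equal medians.

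Of the cytotoxic and NK cell markers, 9 of 23 were higher and 1 lower (9 and 1 adjusted over the list alone), with a median of 0.41, and the direction of the test turned with equal medians and quantile normalization. The cytotoxic and NK cell list had a fry adjusted p of 0.00384 and adjusted p = 0.979 with an estimated correlation. Gzmb, which encodes granzyme B, rose by 2.13 ± 0.20 and the perforin gene Prf1 by 1.97 ± 0.37. The NK receptor gene Ncr1 was 139 ± 41.4 against 127 ± 34.0 (limma adjusted p = 0.665), and with equal medians its sign turned and it was called lower. Of the T cell markers, 3 of 19 were higher and 0 lower (1 and 0 adjusted over the list alone), with a median of 0.56, and the direction of the test turned with equal medians and quantile normalization. The T cell list had a fry adjusted p of 0.0417 and adjusted p = 0.762 with an estimated correlation. The called members were Icos (1.03 ± 0.37), Lck (0.86 ± 0.23) and Cd27 (0.85 ± 0.33), and Cd8a was 6.03 ± 2.85 against 5.39 ± 1.75 (limma adjusted p = 0.886). Of the B cell markers, 3 of 14 were higher and 0 lower (3 and 0 adjusted over the list alone), with a median of 0.29, and the direction of the test turned with equal medians. The B cell list had a fry adjusted p of 0.000245 and adjusted p = 0.762 with an estimated correlation. Cd79b was at 2.33 ± 0.26. Of the checkpoint and regulatory T cell genes, 5 of 15 were higher and 0 lower (5 and 0 adjusted over the list alone), with a median of 0.76, and the direction of the test turned with equal medians and quantile normalization. The checkpoint and regulatory T cell list had a fry adjusted p of 0.00703 and adjusted p = 0.762 with an estimated correlation. Il2ra was at 1.86 ± 0.50. Of the mast cell and eosinophil markers, 2 of 10 were higher and 0 lower (2 and 0 adjusted over the list alone), with a median of 0.54, and the direction of the test turned with equal medians and quantile normalization. The mast cell and eosinophil list had a fry adjusted p of 0.0483 and adjusted p = 0.762 with an estimated correlation. Ccr3 was at 1.28 ± 0.44. Of the genes of alternative activation and immunosuppression, 10 of 19 were higher and 1 lower (10 and 1 adjusted over the list alone), with a median of 0.73, and the direction of the test turned with equal medians. The alternative activation list had a fry adjusted p of 3.5e-05 and adjusted p = 0.762 with an estimated correlation. Of the inflammasome and cell death genes, 5 of 15 were higher and 3 lower (5 and 3 adjusted over the list alone), with a median of 0.15, and the direction of the test turned with equal medians, median-ratio scaling and quantile normalization. The inflammasome and cell death list had a fry adjusted p of 0.0483 and adjusted p = 0.266 with an estimated correlation.

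Of the fibroblast and matrix genes, 9 of 13 were higher and 0 lower (9 and 0 adjusted over the list alone), with a median of 0.48, and the direction of the test turned with equal medians. The fibroblast and matrix list had a fry adjusted p of 2.4e-06 and adjusted p = 0.762 with an estimated correlation. Mmp9 was at 1.96 ± 0.22, Fn1 at 0.87 ± 0.12 and Col1a1 at 0.86 ± 0.17. Of the endothelial genes, 8 of 17 were higher and 0 lower (8 and 0 adjusted over the list alone), with a median of 0.59, and the direction of the test turned with equal medians and quantile normalization. The endothelial list had a fry adjusted p of 1.5e-05 and adjusted p = 0.762 with an estimated correlation. Eng was at 0.97 ± 0.14. Of the epithelial and tumour cell genes, 2 of 10 were higher and 1 lower (2 and 1 adjusted over the list alone), with a median of 0.11, and the direction of the test turned with equal medians, median-ratio scaling and quantile normalization. The epithelial and tumour cell list had a fry adjusted p of 0.0483 and adjusted p = 0.762 with an estimated correlation. Muc1 was at 1.01 ± 0.15. Epcam was 5327 ± 654 against 6213 ± 286 (limma adjusted p = 0.0873) and was called lower with median-ratio scaling and equal medians. Erbb2 was 1930.5 ± 347 against 1353 ± 140.1, a log2 fold change of 0.50 ± 0.13 whose call ended with median-ratio scaling and quantile normalization and whose sign turned with equal medians, and whether its mouse probe reads the rat transcript is not given in the sources used here. Of the proliferation genes, 1 of 4 was higher and 2 lower (1 and 2 adjusted over the list alone), with a median of -0.46. The proliferation list had a fry adjusted p of 0.0483 and adjusted p = 0.266 with an estimated correlation. Birc5 was at -0.54 ± 0.13. Of the reference genes, 20 of which had about the same geometric mean in all tumours, 6 of 21 were higher and 8 lower (6 and 8 adjusted over the list alone), with a median of -0.081. The reference list had a fry adjusted p of 0.13 and adjusted p = 0.0466 with an estimated correlation. Because the geometric mean of 20 of these genes stood level across tumours, the value of the reference list with an estimated correlation restates the shift of the panel's median. Gusb (0.66 ± 0.13), Sap130 (0.67 ± 0.19) and Sdha (0.52 ± 0.12) were called higher as deposited, and their sign turned with equal medians, and for Sdha with quantile normalization as well, while Rpl19 was at -0.54 ± 0.13. The fry test asks whether a list's members move one way on balance and does not compare the list with other genes. Leaving out 1 tumour at a time ended the call of Cxcl10 (without isotype antibody 4, highest adjusted p 0.0541), Icos (without isotype antibody 2 or 4 or anti-rHER2 ISAC 1, 3 or 5, highest adjusted p 0.0958) and Ccr3 (without isotype antibody 2 or anti-rHER2 ISAC 1, highest adjusted p 0.0729). The call of Il12b ended in 7 of 10 fits, those that left out isotype antibody 1, 2, 4 or 5 or anti-rHER2 ISAC 1, 3 or 5 (highest adjusted p 0.11). The call of Cd27 ended in 7 of 10 fits, those that left out isotype antibody 1, 2 or 4 or anti-rHER2 ISAC 1, 2, 3 or 4 (highest adjusted p 0.132).

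**Figure D2:**
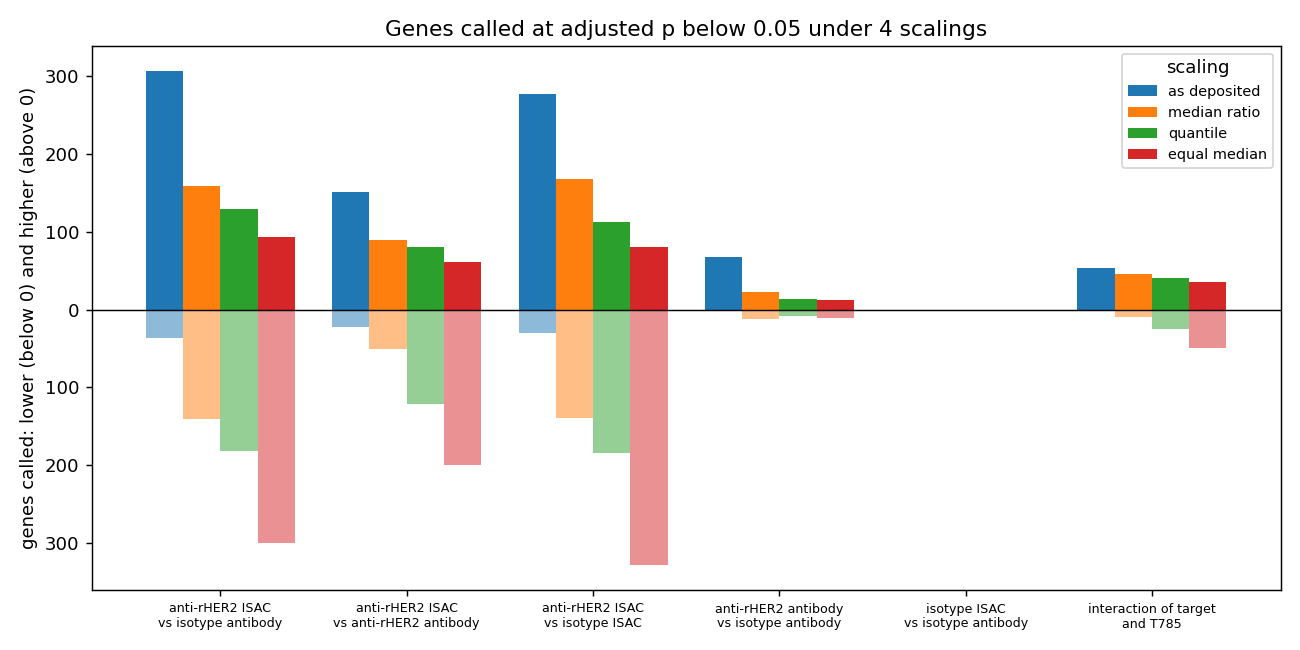
Number of genes called higher (bars above 0) and lower (bars below 0) at a limma adjusted p below 0.05 in each of the 6 comparisons, under the deposited scaling and 3 others (n = 5 tumours per group). For the anti-rHER2 ISAC against the isotype antibody, 307 genes were higher and 36 lower as deposited, and with equal medians most calls were lower, with 93 higher and 301 lower.

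The comparison of the anti-rHER2 ISAC with anti-rHER2 alone asks what T785 added on the targeting antibody. Chemokine genes were among the highest, with Ccl3 (3.67 ± 0.41), Ccl4 (3.43 ± 0.32), Cxcl13 (3.29 ± 0.41), Ccl5 (3.28 ± 0.28), Ccl12 (2.67 ± 0.29) and Ccl2 (2.2 ± 0.27), and Ccl12 rose from 119 ± 54.6 to 723 ± 235. Fcgr4 rose from 125 ± 26.1 to 653 ± 126, a log2 fold change of 2.38 ± 0.15 (limma adjusted p = 2.7e-09), with 5 of 5 tumours above every anti-rHER2 tumour. The myeloid genes S100a8 (3.10 ± 0.30), Fpr2 (2.77 ± 0.27), Cxcr2 (2.13 ± 0.36), Il1rn (2.11 ± 0.18) and Itgam (1.89 ± 0.18) rose as well, as did Il10 (2.00 ± 0.33), Gzmb (1.78 ± 0.20) and Prf1 (1.66 ± 0.37). The MHC class II genes H2-Ea-ps (-1.49 ± 0.28), H2-Ab1 (-1.30 ± 0.21), H2-Eb1 (-1.21 ± 0.34) and H2-Aa (-0.86 ± 0.23) were lower. H2-Ea-ps is named as a pseudogene, so its value is uncertain where its probe also reads related transcripts. These differences take in any rise with anti-rHER2 alone. H2-Ea-ps averaged 72.3, 135 and 48.8 with the isotype antibody, anti-rHER2 and the anti-rHER2 ISAC, and H2-Eb1 24.9, 39.2 and 17.2. In the same order H2-Ab1 averaged 2417, 2486 and 1006 and H2-Aa 4902, 5455 and 2974. The other genes with the lowest fold changes were Ccl17 (-1.64 ± 0.43), Lyz2 (-1.11 ± 0.20), Ifnb1 (-1.11 ± 0.36), Tnfsf18 (-0.91 ± 0.32) and Ccl1 (-0.87 ± 0.26), and Ifnb1 was close to the floor, at 1.87 ± 0.992 against 5.28 ± 2.12. Lyz2 averaged 2424 with the isotype antibody, 3917 with anti-rHER2 and 1809 with the anti-rHER2 ISAC.

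Of the MHC class II genes, 0 of 11 were higher and 6 lower (1 and 6 adjusted over the list alone), with a median of -0.61. The MHC class II list had a fry adjusted p of 0.00747 and adjusted p = 0.388 with an estimated correlation. Of the Fc-gamma and effector genes, 8 of 10 were higher and 0 lower (8 and 0 adjusted over the list alone), with a median of 0.98. The Fc-gamma and effector list had a fry adjusted p of 1.8e-06 and adjusted p = 0.388 with an estimated correlation. Fcgr1 was at 1.01 ± 0.19 and Fcer1g at 1.48 ± 0.14. Of the monocyte-recruiting chemokine genes, 7 of 14 were higher and 0 lower (7 and 0 adjusted over the list alone), with a median of 0.87. The monocyte-recruiting chemokine list had a fry adjusted p of 4.5e-05 and adjusted p = 0.582 with an estimated correlation. Of the type I interferon response genes, 11 of 28 were higher and 1 lower (11 and 1 adjusted over the list alone), with a median of 0.45. The type I interferon list had a fry adjusted p of 0.0173 and adjusted p = 0.873 with an estimated correlation. Ifitm1 was at 1.93 ± 0.26 and Oasl1 at 1.18 ± 0.23. Of the complement genes, 7 of 25 were higher and 1 lower (7 and 1 adjusted over the list alone), with a median of 0.35, and the direction of the test turned with equal medians. The complement list had a fry adjusted p of 0.0173 and adjusted p = 0.873 with an estimated correlation. C5ar1 was at 1.66 ± 0.23 and C3ar1 at 1.26 ± 0.16. Of the inflammatory cytokine genes, whose median was negative while their mean and the direction of the test were positive, 3 of 18 were higher and 0 lower (3 and 0 adjusted over the list alone), with a median of -0.027, and the direction of the test turned with equal medians. The inflammatory cytokine list had a fry adjusted p of 0.00747 and adjusted p = 0.873 with an estimated correlation. Cxcl9 (1.53 ± 0.38) and Tlr8 (0.64 ± 0.17) were higher, the latter not with equal medians or quantile normalization. Tnf was 9.83 ± 7.87 against 3.35 ± 0.609 (1.10 ± 0.35) and lost its call with median-ratio scaling and equal medians, and Chil3 (2.1 ± 0.73) lost its call with these and quantile normalization. Erbb2 (0.24 ± 0.13), Tlr7 (0.15 ± 0.27), Fcgr3 (0.012 ± 0.21), Cd40 (0.50 ± 0.24), Il12b (0.93 ± 0.33), Cxcl10 (0.50 ± 0.31), Cd8a (-0.31 ± 0.36) and Ncr1 (0.049 ± 0.22) did not pass, nor did Cd86 (-0.14 ± 0.21), which was called lower with equal medians and quantile normalization.

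In total 151 genes were higher and 23 lower, and the median log2 fold change of all genes was 0.16. Higher and lower calls numbered 89 and 51 with median-ratio scaling, 80 and 121 with quantile normalization and 61 and 200 with equal medians, where the median of all genes was -0.028, -0.099 and -0.27. Of the 174 calls, 112, 101 and 84 were made there in the same direction. Of the 34 named genes called, which were chosen mainly for large fold changes, 31 kept the call and direction under these 3 scalings and under equal means of the fixed reference list. With these scalings 5, 4 and 3 of the 15 list calls were made in the same direction, and 0, 1 and 2 in the opposite direction. Leaving out a tumour took the 15 list calls to 8 without anti-rHER2 antibody 2 and 7 without anti-rHER2 ISAC 1. With 1 tumour left out at a time, calls were lost for Ccl1 (without anti-rHER2 antibody 4 or anti-rHER2 ISAC 1 or 4, highest adjusted p 0.0731) and Tnf (without anti-rHER2 antibody 1, 2 or 4 or anti-rHER2 ISAC 1 or 3, highest adjusted p 0.0895). The call of Chil3 ended in 8 of 10 fits, those that left out anti-rHER2 antibody 1, 2, 3 or 5 or anti-rHER2 ISAC 1, 2, 3 or 5 (highest adjusted p 0.146). The call of Ifnb1 ended in 6 of 10 fits, those that left out anti-rHER2 antibody 1, 3, 4 or 5 or anti-rHER2 ISAC 1 or 3 (highest adjusted p 0.0906). The call of Tnfsf18 ended in 9 of 10 fits, those that left out anti-rHER2 antibody 1, 2, 3, 4 or 5 or anti-rHER2 ISAC 1, 2, 3 or 4 (highest adjusted p 0.119).

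The comparison of the anti-rHER2 ISAC with the isotype ISAC asks what the targeting antibody added when T785 was attached to both. S100a8 was 1225 ± 442 against 39.1 ± 11.2, a log2 fold change of 4.89 ± 0.30 (limma adjusted p = 7.6e-10), and Cxcr2 113 ± 35.1 against 3.66 ± 2.2. Among the next highest genes were Ccl3 (4.21 ± 0.41), Ccl5 (3.98 ± 0.28), Ccl4 (3.81 ± 0.32), Fpr2 (3.62 ± 0.27), Chil3 (3.08 ± 0.73), Cxcl13 (2.94 ± 0.41), Il10 (2.77 ± 0.33), Ccl12 (2.70 ± 0.29) and Slc11a1 (2.64 ± 0.20). The lowest genes that passed were Ccl17 (-1.85 ± 0.43), Tnfsf18 (-1.34 ± 0.32), Cxcl15 (-1.03 ± 0.25), H2-Ab1 (-0.98 ± 0.21), Birc5 (-0.93 ± 0.13), Aire (-0.89 ± 0.29), Cd207 (-0.89 ± 0.30) and Ccl1 (-0.85 ± 0.26), of which Aire was close to the floor, at 1.48 ± 0.373 against 3.71 ± 1.28. Fcgr4 rose by 2.33 ± 0.15, Fcgr1 by 1.70 ± 0.19, Itgam by 2.60 ± 0.18, Fcer1g by 2.02 ± 0.14 and Csf3r, which encodes the G-CSF receptor, by 2.62 ± 0.27.

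Of the Fc-gamma and effector genes, 9 of 10 were higher and 0 lower (10 and 0 adjusted over the list alone), with a median of 1.48. The Fc-gamma and effector list had a fry adjusted p of 1.6e-08 and adjusted p = 0.217 with an estimated correlation. Of the monocyte-recruiting chemokine genes, 11 of 14 were higher and 0 lower (12 and 0 adjusted over the list alone), with a median of 1.67. The monocyte-recruiting chemokine list had a fry adjusted p of 2.7e-07 and adjusted p = 0.346 with an estimated correlation. Ccl2 was at 2.56 ± 0.27. Of the type I interferon response genes, 18 of 28 were higher and 0 lower (20 and 0 adjusted over the list alone), with a median of 0.78. The type I interferon list had a fry adjusted p of 0.000233 and adjusted p = 0.896 with an estimated correlation. Ifitm1 was at 2.52 ± 0.26 and Oasl1 at 1.59 ± 0.23. Of the cytotoxic and NK cell markers, 7 of 23 were higher and 1 lower (7 and 0 adjusted over the list alone), with a median of 0.48, and the direction of the test turned with equal medians. The cytotoxic and NK cell list had a fry adjusted p of 0.00174 and adjusted p = 0.929 with an estimated correlation. Gzmb was at 2.17 ± 0.20 and Prf1 at 2.1 ± 0.37. Of the complement genes, 14 of 25 were higher and 2 lower (16 and 3 adjusted over the list alone), with a median of 0.78. The complement list had a fry adjusted p of 6.3e-05 and adjusted p = 0.896 with an estimated correlation. C5ar1 was at 2.12 ± 0.23 and C3ar1 at 2.06 ± 0.16. Of the dendritic cell markers, whose median was negative while their mean and the direction of the test were positive, 3 of 14 were higher and 2 lower (3 and 2 adjusted over the list alone), with a median of -0.038, and the direction of the test turned with equal medians and quantile normalization. The dendritic cell list had a fry adjusted p of 0.0387 and adjusted p = 0.896 with an estimated correlation. Tlr8 (1.31 ± 0.17), Cxcl9 (2.37 ± 0.38) and Il12b (1.27 ± 0.33) were higher, the last not with equal medians. Fcgr3 (0.64 ± 0.21) and Cd40 (0.71 ± 0.24) were called higher as deposited and under none of median-ratio scaling, quantile normalization and equal medians, and with equal medians their sign turned. Cxcl10 (0.75 ± 0.31), Tnf (0.48 ± 0.35), Tlr7 (0.43 ± 0.27) and Cd8a (0.43 ± 0.36) did not pass. Erbb2 (0.13 ± 0.13), Cd86 (0.10 ± 0.21), Ncr1 (0.18 ± 0.22) and Ifnb1 (-0.33 ± 0.36) did not pass as deposited and were called lower with equal medians, where the sign of the first 3 turned. The sign of Cd86 turned with quantile normalization as well, and it was called lower there.

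In total 277 genes were higher and 30 lower, and the median log2 fold change of all genes was 0.29. Higher and lower calls numbered 168 and 139 with median-ratio scaling, 113 and 185 with quantile normalization and 81 and 329 with equal medians, where the median of all genes was -0.054, -0.12 and -0.42. Of the 307 calls, 198, 141 and 111 were made there in the same direction and 1 in the opposite direction with quantile normalization and 23 with equal medians. Of the 36 named genes called, 33 kept the call and direction under these 3 scalings and under equal means of the fixed reference list. With these scalings 13, 9 and 5 of the 22 list calls were made in the same direction, and 0, 2 and 7 in the opposite direction. With 1 tumour left out at a time, calls were lost for Aire (without isotype ISAC 4 or 5 or anti-rHER2 ISAC 3, highest adjusted p 0.056), Cd207 (without isotype ISAC 4 or 5 or anti-rHER2 ISAC 3 or 4, highest adjusted p 0.0778) and Fcgr3 (without anti-rHER2 ISAC 3, highest adjusted p 0.0577). The same was so for Cd40 (without isotype ISAC 1 or anti-rHER2 ISAC 1 or 3, highest adjusted p 0.0748).

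Anti-rHER2 alone was compared with the isotype antibody to ask what the targeting antibody did without a payload. Cxcr2 rose from 3.74 ± 2.4 to 24.9 ± 6.22, a log2 fold change of 2.57 ± 0.36 (limma adjusted p = 0.000453), and S100a8 from 30.4 ± 8.43 to 139 ± 41.3 (2.14 ± 0.30). Ptgs2, which encodes cyclooxygenase-2, rose by 1.84 ± 0.49, the cytokine gene Osm by 1.69 ± 0.37 and the beta-glucan receptor gene Clec7a by 1.61 ± 0.26. The chemokine gene Cxcl1 (-0.89 ± 0.22) was among the genes called lower. Of the monocyte and macrophage markers, 8 of 17 were higher and 0 lower (10 and 0 adjusted over the list alone), with a median of 0.57. The monocyte and macrophage list had a fry adjusted p of 0.00287 and adjusted p = 0.482 with an estimated correlation. Cd68 was at 0.97 ± 0.15, Emr1 at 0.83 ± 0.22 and Siglec1 at 0.81 ± 0.20. Of the Fc-gamma and effector genes, 4 of 10 were higher and 0 lower (8 and 0 adjusted over the list alone), with a median of 0.51. The Fc-gamma and effector list had a fry adjusted p of 0.00948 and adjusted p = 0.939 with an estimated correlation. Itgb2 was at 0.78 ± 0.17 and Syk at 0.78 ± 0.20. Fcgr4 was 125 ± 26.1 against 129.9 ± 15.9 (limma adjusted p = 0.832). Il1b (1.27 ± 0.31), Csf3r (1.06 ± 0.27), Tlr8 (1.00 ± 0.17), Mmp9 (0.91 ± 0.22) and Fn1 (0.40 ± 0.12) were higher. Ccl2 (0.24 ± 0.27), Cxcl9 (0.96 ± 0.38), Cxcl10 (0.45 ± 0.31), Fcgr1 (0.50 ± 0.19), Tnf (-0.68 ± 0.35) and Erbb2 (0.26 ± 0.13) did not pass.

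In total 68 genes were higher and 2 lower, and the median log2 fold change of all genes was 0.20. Higher and lower calls numbered 22 and 12 with median-ratio scaling, 14 and 8 with quantile normalization and 12 and 11 with equal medians, where the median of all genes was 0.0077, -0.015 and -0.079. Of the 70 calls, 24, 16 and 14 were made there in the same direction. Of the 16 named genes called, 6 kept the call and direction under these 3 scalings and under equal means of the fixed reference list. Ptgs2, Emr1, Mmp9 and Fn1 lost it under each of the 3, Siglec1, Il1b, Syk and Csf3r with quantile normalization and equal medians, and Osm and Itgb2 with quantile normalization. In the same direction 3, 4 and 2 of the 11 list calls were made there, and 0 in the opposite direction. Counts moved by more than 1.5 times in some fits that left out a tumour, to 43 without isotype antibody 1, 23 without isotype antibody 2, 33 without isotype antibody 4, 32 without anti-rHER2 antibody 1, 22 without anti-rHER2 antibody 4 and 29 without anti-rHER2 antibody 5 for genes and to 7 without isotype antibody 4 for lists. Leaving out 1 tumour at a time ended the call of Ptgs2 (without isotype antibody 1 or 2 or anti-rHER2 antibody 3, 4 or 5, highest adjusted p 0.0675), Cxcl1 (without isotype antibody 2, highest adjusted p 0.0555) and Emr1 (without isotype antibody 1, 2 or 4 or anti-rHER2 antibody 1 or 4, highest adjusted p 0.0776). The same was so for Siglec1 (without isotype antibody 2 or anti-rHER2 antibody 1 or 4, highest adjusted p 0.0627), Il1b (without isotype antibody 2 or anti-rHER2 antibody 4 or 5, highest adjusted p 0.06) and Syk (without isotype antibody 2 or anti-rHER2 antibody 4 or 5, highest adjusted p 0.064). The same was so for Csf3r (without isotype antibody 2 or anti-rHER2 antibody 1, 4 or 5, highest adjusted p 0.0737) and Mmp9 (without isotype antibody 4 or anti-rHER2 antibody 4 or 5, highest adjusted p 0.0547). The call of Fn1 ended in 9 of 10 fits, those that left out isotype antibody 1, 2, 3, 4 or 5 or anti-rHER2 antibody 2, 3, 4 or 5 (highest adjusted p 0.126).

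The isotype ISAC was compared with the isotype antibody to ask what T785 did on an antibody without the HER2 target. Fcgr4 was 128 ± 15.1 against 129.9 ± 15.9, Ccl2 93.4 ± 23.8 against 101 ± 21.6, Cxcl9 84.9 ± 47.6 against 74.2 ± 28.8 and Tlr8 97.7 ± 11.3 against 79.2 ± 20.5. Erbb2 was 1752 ± 238 against 1353 ± 140.1 (limma adjusted p = 0.718). Chil3 was at 0.90 ± 0.73, Ptgs2 at 0.88 ± 0.49 and Ccl3 at -0.69 ± 0.41, with limma adjusted p values of 0.928, 0.843 and 0.843. No gene passed limma at an adjusted p below 0.05, edgeR on the recovered counts called 0 genes as well, and 47 of 770 genes had an unadjusted p below 0.05. The gene with the smallest p, chosen after its values were seen, was the interferon-lambda gene Ifnl2, close to the floor at 4.76 ± 0.912 against 1.52 ± 0.601, with a log2 fold change of 1.21 and a limma adjusted p of 0.306, or 0.0319 with only these 2 groups in the fit. The 95% confidence interval of a log2 fold change reached 0.43 to either side at the median gene. None of the 25 lists passed fry, the smallest adjusted p being 0.805, none had an unadjusted fry p below 0.05, and camera called 0.

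The interaction asks whether T785 changed expression by another amount on anti-rHER2 than on the isotype antibody. Ccl3 had the highest interaction, 4.36 ± 0.58 (limma adjusted p = 5.1e-05), with signals of 12.2 ± 5.75, 6.91 ± 2.59, 11.5 ± 5.92 and 148 ± 68.4 in the isotype antibody, isotype ISAC, anti-rHER2 and anti-rHER2 ISAC tumours. It was followed by Cxcl13 (3.47 ± 0.57), Ccl4 (3.38 ± 0.45), Ccl5 (3.29 ± 0.40) and Ccl12 (2.94 ± 0.41). Fcgr4 (2.4 ± 0.21, limma adjusted p = 7.8e-07), Fcgr1 (1.20 ± 0.27), Fcer1g (1.51 ± 0.20) and Itgam (1.84 ± 0.26) passed, as did Fpr2 (2.83 ± 0.38), S100a8 (2.76 ± 0.42), Il10 (2.59 ± 0.47), Ccl2 (2.32 ± 0.38), Cxcr2 (2.12 ± 0.51), Gzmb (1.82 ± 0.29), Prf1 (1.78 ± 0.53), C5ar1 (1.72 ± 0.33), Ifitm1 (1.53 ± 0.37) and C3ar1 (1.33 ± 0.22). The negative calls were H2-Ea-ps (-1.57 ± 0.39) and H2-Ab1 (-1.02 ± 0.29). Of the monocyte-recruiting chemokine genes, 7 of 14 were higher and 0 lower (7 and 0 adjusted over the list alone), with a median of 1.16. The monocyte-recruiting chemokine list had a fry adjusted p of 0.000576 and adjusted p = 0.399 with an estimated correlation. Of the Fc-gamma and effector genes, 6 of 10 were higher and 0 lower (6 and 0 adjusted over the list alone), with a median of 1.06. The Fc-gamma and effector list had a fry adjusted p of 0.000226 and adjusted p = 0.399 with an estimated correlation. Tlr8 (0.31 ± 0.24), Cxcl9 (1.41 ± 0.53), Cxcl10 (0.30 ± 0.44), Tnf (1.16 ± 0.50), Il12b (1.32 ± 0.47) and Erbb2 (-0.12 ± 0.18) did not pass.

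In total the interaction was positive for 53 genes and negative for 2, with a median of 0.11 over all genes. Higher and lower calls numbered 46 and 10 with median-ratio scaling, 41 and 25 with quantile normalization and 36 and 49 with equal medians, where the median of all genes was -0.040, -0.10 and -0.32. Of the 55 calls, 48, 42 and 38 were made there in the same direction. Of the 21 named genes called, 20 kept the call and direction under these 3 scalings and under equal means of the fixed reference list, and Prf1 lost its call under each of the 3. List calls rose from 2 to 5 without anti-rHER2 antibody 4 and 7 without anti-rHER2 ISAC 2. With 1 tumour left out at a time, a call ended for H2-Ab1 in 11 of 20 fits, those that left out isotype antibody 2 or 4 or isotype ISAC 3, 4 or 5 or anti-rHER2 antibody 1, 4 or 5 or anti-rHER2 ISAC 2, 4 or 5 (highest adjusted p 0.0797). The call of Prf1 ended in 16 of 20 fits, those that left out isotype antibody 1, 2, 3 or 4 or isotype ISAC 1, 2, 3 or 5 or anti-rHER2 antibody 1, 2, 3 or 4 or anti-rHER2 ISAC 1, 3, 4 or 5 (highest adjusted p 0.0924).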

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

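The tests of the lowest count over the other scalings, of a single factor per tumour, of dilution and of dendritic cell markers were chosen only after the result was seen, and those of depth, of a single tumour and of other splits of the samples before it. In the anti-rHER2 ISAC against the isotype antibody, 307 of 343 called genes were higher. A difference in depth stays open, since 287 of the 307 (93.5%) were still called higher once every tumour was thinned to the same signal per count, but thinning keeps each gene's expected signal and so bears only on counting noise and the floor. Scaling on the reference genes stays open, since over 4 other scalings as few as 93 of the 307 (30.3%) were still called higher, the lowest with equal medians. For the 218 that lost the call under at least 1 of them, scaling and a response to the conjugate cannot be told apart without a control outside the panel's genes, while 89 kept it under each.

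Of 11 MHC class II genes, 6 were lower in the anti-rHER2 ISAC than in the anti-rHER2 antibody tumours, with a list median of -0.61 (fry adjusted p = 0.00747). A single factor per tumour moves all genes alike, and the median of all genes lay 0.774 above that of the list, more than the list's interquartile range of 0.728, which argues against it, although camera, which sets a list against the other genes, gave p = 0.0276 and adjusted p = 0.388 with an estimated correlation. Dilution by incoming cells stays open. The epithelial, fibroblast and endothelial medians were 0.017, 0.24 and 0.22 as deposited, so none was lower there, but with equal medians they were -0.41, -0.19 and -0.22. As deposited, the lowest of them lay 0.629 above that of the list, within the list's interquartile range. That range is a spread between genes and not the error of this difference. Fewer dendritic cells also stay open, since of 5 called markers outside the list 2 were lower, Ccl17 (-1.64 ± 0.43) and Cd83 (-0.77 ± 0.24), and 3 higher, Ccr7 (1.15 ± 0.30), Clec4a2 (1.47 ± 0.19) and Itgax (0.74 ± 0.17). A lower level per cell after treatment was not tested. The difference also takes in any rise with anti-rHER2 alone. H2-Ea-ps averaged 135 with anti-rHER2, against 72.3 with the isotype antibody and 48.8 with the anti-rHER2 ISAC. For H2-Ab1 these means were 2486, 2417 and 1006. What part of the list's shift such a rise makes was not tested.

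In anti-rHER2 against the isotype antibody, 68 genes were called higher. With 1 tumour left out at a time, the median fold change of these 68 kept at least 93.3% of its value, the lowest being without isotype antibody 2. The 68 were called with all tumours in the fit, which favours genes that rest on no single tumour, so this cannot settle the part of a single tumour. The count of calls fell in some of these fits, to 43 without isotype antibody 1, 23 without isotype antibody 2, 33 without isotype antibody 4, 32 without anti-rHER2 antibody 1, 22 without anti-rHER2 antibody 4 and 29 without anti-rHER2 antibody 5. Scaling on the reference genes stays open here too, since 12 of the 68 (17.6%) were still called higher with equal medians, the lowest of the 4 other scalings. For the 59 that lost the call under at least 1 of them, scaling and a response to the antibody cannot be told apart, while 9, Cxcr2 and S100a8 among them, kept it under each.

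Each comparison was repeated over 100 splits of its tumours, the real one included. Chance can be excluded for the gene counts of the comparisons of 2 groups that had calls, where 1 of 100 splits, the real one, gave as many: 343 for the anti-rHER2 ISAC against the isotype antibody (highest other 213), 174 for the anti-rHER2 ISAC against anti-rHER2 (highest other 107), 307 for the anti-rHER2 ISAC against the isotype ISAC (highest other 234) and 70 for anti-rHER2 against the isotype antibody (highest other 4). For the interaction 1 of 100 splits, the real one, gave as many as the real 55 genes (highest other 3). Its splits mixed the tumours of all 4 groups and so also removed the separate effects of target and T785. They cannot say whether the interaction calls arose by chance. For lists the real split gave the most calls, 23, 22 and 11, in the anti-rHER2 ISAC against the isotype antibody, the anti-rHER2 ISAC against the isotype ISAC and anti-rHER2 against the isotype antibody (1 of 100 splits each, highest other 21, 16 and 10). Leaving out 1 tumour took these to as few as 16, 18 and 7. Chance can be excluded for the 22. For the 23 and the 11 it is not taken as excluded, since another split came close and the left-out counts fell below it. In the anti-rHER2 ISAC against anti-rHER2, 2 of 100 splits, the real one included, gave at least the real 15 list calls. That share was under the limit set beforehand. The other split gave 17, more than the real one, so chance is not excluded for that count. In the interaction 2 of 100 splits gave at least the real 2 list calls and the highest other gave 13, and here too its splits cannot test the interaction. For the isotype ISAC against the isotype antibody, with 0 genes and 0 lists, 100 of 100 splits gave as many, which a real count of 0 makes certain, so the splits say nothing about chance there, and the highest other gave 8 genes and 2 lists.

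The effect of T785 differed between the antibodies by the interaction test for 55 genes. The named genes among them, with the interaction on the log2 scale, were Ccl3 (4.36), Cxcl13 (3.47), Ccl4 (3.38), Ccl5 (3.29), Ccl12 (2.94), Fpr2 (2.83), S100a8 (2.76), Il10 (2.59), Fcgr4 (2.4), Ccl2 (2.32), Cxcr2 (2.12), Itgam (1.84), Gzmb (1.82), Prf1 (1.78), C5ar1 (1.72), Ifitm1 (1.53), Fcer1g (1.51), C3ar1 (1.33), Fcgr1 (1.20), H2-Ab1 (-1.02) and H2-Ea-ps (-1.57).

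In 29 of 356 combinations of a named gene and a group, 1 tumour stood apart from the other 4 by a gap of more than 0.71 of the group's range, on the linear signal. Independent values with a normal spread would give about 17.8, 1 in 20. Linear signals can be skewed to the high side and genes of 1 tumour are not independent, so the excess over 17.8 is not a test of chance. Each of the 29 is given with the gap as a share of the range, the tumour's signal and the range of the others. In anti-rHER2 antibody replicate 4 these were C5ar1 (high, 0.751, 186 against 94.2 to 117), Ccl1 (high, 0.736, 28.6 against 14.0 to 17.9), Chil3 (high, 0.760, 136 against 4.13 to 35.7) and Gusb (high, 0.767, 305 against 243 to 257). Also in anti-rHER2 antibody replicate 4 this was Osm (high, 0.718, 59.2 against 20.5 to 31.4). In anti-rHER2 ISAC replicate 3 these were Ccl2 (high, 0.822, 1152 against 385 to 522), Ccl3 (high, 0.810, 268 against 95.2 to 128), Ccl4 (high, 0.751, 153 against 71.3 to 91.6) and Clec4n (high, 0.766, 82.5 against 42.8 to 52.1). Also in anti-rHER2 ISAC replicate 3 these were Mmp9 (high, 0.758, 89.8 against 52.7 to 61.6), Ncr1 (high, 0.749, 210.5 against 105 to 132) and Tnf (high, 0.836, 23.7 against 4.48 to 7.63). In anti-rHER2 antibody replicate 5 these were Cd83 (high, 0.746, 228 against 119 to 147), Cxcl15 (high, 0.778, 29.7 against 16.9 to 19.7), Lyz2 (high, 0.772, 5641 against 3261 to 3803) and Prf1 (high, 0.798, 50.3 against 26.8 to 31.6). In anti-rHER2 antibody replicate 1 these were Cxcl10 (high, 0.737, 188 against 76.2 to 106) and Il2ra (high, 0.723, 54.9 against 10.3 to 22.7). In anti-rHER2 ISAC replicate 2 this was Cxcl10 (low, 0.752, 98.5 against 150.0 to 167). In isotype antibody replicate 4 this was Gbp5 (low, 0.770, 33.2 against 47.6 to 51.9). In isotype ISAC replicate 1 these were Gzmb (low, 0.789, 43.0 against 72.7 to 80.6) and Ifnb1 (high, 0.782, 7.65 against 1.14 to 2.56). In isotype ISAC replicate 3 this was Icos (high, 0.816, 23.9 against 11 to 13.4). In anti-rHER2 ISAC replicate 1 this was Ifit3 (high, 0.741, 1619 against 902 to 1088). In isotype ISAC replicate 5 these were Il1rn (high, 0.763, 84.4 against 61.6 to 67) and Mmp9 (high, 0.812, 25.7 against 17.2 to 18.8). In isotype antibody replicate 5 this was Prf1 (low, 0.787, 9.71 against 29.5 to 34.8). In anti-rHER2 antibody replicate 3 this was Ptgs2 (high, 0.719, 116 against 58.6 to 74.9). In anti-rHER2 ISAC replicate 5 this was Tnfsf18 (high, 0.794, 56.0 against 17.8 to 25.7).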

How the results depend on the processing

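Median-ratio scaling and edgeR were the tests chosen only after the result was seen. In this part ISAC alone stands for the anti-rHER2 ISAC, and the 6 comparisons come in the order of the methods. Requiring an absolute log2 fold change of at least 1 left 139, 63, 126 and 13 genes in the first 4, by its construction. In anti-rHER2 against the isotype antibody, 23 genes were called with equal medians, 34 with median-ratio scaling, 22 with quantile normalization, 33 with only the compared groups in the fit and 21 with an unmoderated 2-group test with unequal variances, against 70. With only the compared groups 1 gene was called for the isotype ISAC against the isotype antibody, and with equal medians 85 for the interaction. Apart from left-out tumours, the other alternatives kept each gene count within 1.5 times. List calls in the ISAC against isotype antibody numbered 14 with equal medians and 10 with quantile normalization, against 23. They were 6 with median-ratio scaling and 7 with quantile normalization against anti-rHER2, and 14 with quantile normalization against the isotype ISAC. For anti-rHER2 against the isotype antibody they were 4, 5, 6 and 7 with equal medians, median-ratio scaling, quantile normalization and only the compared groups. For the interaction they were 9 with equal medians, 6 with quantile normalization and 4 with array weights. With camera and an estimated correlation 1, 0, 0, 1, 0 and 0 lists were called, the single call of 2 comparisons being the reference genes. The geometric mean of 20 of these was level across tumours, so that call restates the shift of the panel's median (0.36 and 0.20). Apart from the fold threshold, the cause of these moves of gene and list counts was not tested.

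Leaving out 1 tumour at a time gave 303 to 360, 118 to 184, 262 to 317, 22 to 79, 0 to 0 and 47 to 67 genes and 16 to 21, 7 to 18, 18 to 22, 7 to 13, 0 to 0 and 2 to 7 lists in the 6 comparisons. With a replicate block 342, 162, 298, 72, 0 and 59 genes and 22, 15, 22, 11, 0 and 2 lists were called, and of the named genes 5 calls were lost and 1 gained. In the ISAC against anti-rHER2 the lost calls were Chil3 (limma adjusted p = 0.0773), Tnfsf18 (limma adjusted p = 0.0613) and Tnf (limma adjusted p = 0.0533) and the gained call was Il12b (limma adjusted p = 0.0459), and the others lost were Fn1 (limma adjusted p = 0.055) in anti-rHER2 against the isotype antibody and Prf1 (limma adjusted p = 0.0699) in the interaction. Tumours with the same number correlated at -0.135 to 0.253 after group means were removed, 4, 2, 0, 2 and 2 of 5 pairs in the first 5 comparisons were over 0.1, and 5, 2, 2, 4 and 5 of 10 tumours correlated best with their own number, where chance gives about 2. Since no comparison had all 5 pairs over 0.1, the numbers were not taken to pair the tumours. That rule is not a test, so a weaker link between tumours of the same number stays open. Of the 175 calls of named genes, 19 were lost with median-ratio scaling, 29 with quantile normalization (1 with its sign turned), 33 with equal medians (6 with their sign turned), 3 with array weights and 3 with edgeR, and 13 of 154 with only the compared groups. DESeq2, planned for raw counts only, was not run, and the unmoderated test was not planned for the interaction. A signal near the floor of 1 rests on a few counts, so changes of Ifnb1, Ccl17, Aire and Ifnl2 are uncertain. Other named genes were low as well. Group means of Cd8a, Cd27 and Tnf lay between 3.29 and 9.83, so their calls, or lack of a call, also rest on few counts. With the isotype antibody Cxcr2, Cxcl13, Ccl4 and Il10 averaged 3.74, 5.33, 5.46 and 4.46, which makes the size of their fold changes uncertain.

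The sign of a named gene's log2 fold change turned in these cases, among genes called as deposited or under the scaling. The cause was not tested beyond the shift that each scaling makes. Turns of named genes called neither as deposited nor under the scaling are not listed. In the ISAC against isotype antibody these were Erbb2 -0.22, Ncr1 -0.59, Sap130 -0.046, Sdha -0.19 and Gusb -0.058 with equal medians and Sdha -0.062 with quantile normalization. In the ISAC against isotype ISAC they were Erbb2 -0.58, Fcgr3 -0.072, Cd40 -0.0034, Cd86 -0.61 and Ncr1 -0.53 with equal medians and Cd86 -0.58 with quantile normalization. Turns of lists called by fry neither as deposited nor under the scaling are likewise not listed. For the other lists the direction of the test turned with a scaling as follows, each list with its median under that scaling, whose sign can differ from that of the test. Type I interferon -0.016, interferon-gamma 0.18, inflammatory cytokines -0.27, NF-kB and TLR signalling -0.26, dendritic cell -0.62, T cell -0.15, cytotoxic and NK cell -0.30, B cell -0.42, checkpoints 0.049, co-stimulation -0.30, MHC class I 0.062, inflammasome and cell death -0.56, mast cell and eosinophil -0.17, endothelial and vascular genes -0.13, fibroblast and matrix genes -0.24, epithelial and tumour cell genes -0.61 and alternative activation 0.020 turned with equal medians in the ISAC against isotype antibody. NF-kB and TLR signalling -0.17, dendritic cell -0.48, T cell -0.070, cytotoxic and NK cell -0.071, checkpoints 0.33, co-stimulation -0.014, inflammasome and cell death -0.23, mast cell and eosinophil 0.17, endothelial and vascular genes -0.099 and epithelial and tumour cell genes -0.16 turned with quantile normalization in the ISAC against isotype antibody. Inflammasome and cell death -0.23 and epithelial and tumour cell genes -0.28 turned with median-ratio scaling in the ISAC against isotype antibody. Inflammatory cytokines -0.46, NF-kB and TLR signalling -0.21, monocyte and macrophage -0.055, dendritic cell -0.56, cytotoxic and NK cell -0.094, B cell -0.24, MHC class I 0.10, complement -0.082, inflammasome and cell death -0.40, endothelial and vascular genes -0.22, fibroblast and matrix genes -0.19, epithelial and tumour cell genes -0.41, alternative activation -0.080 and reference genes -0.45 turned with equal medians in the ISAC against anti-rHER2. NF-kB and TLR signalling -0.14, inflammasome and cell death -0.20, endothelial and vascular genes -0.17, fibroblast and matrix genes 0.033 and reference genes -0.17 turned with quantile normalization in the ISAC against anti-rHER2. Reference genes -0.20 turned with median-ratio scaling in the ISAC against anti-rHER2. Inflammatory cytokines -0.54, NF-kB and TLR signalling -0.30, dendritic cell -0.75, T cell -0.13, cytotoxic and NK cell -0.23, B cell -0.31, checkpoints -0.21, co-stimulation -0.28, MHC class I 0.043, inflammasome and cell death -0.69, mast cell and eosinophil -0.30, endothelial and vascular genes -0.27, fibroblast and matrix genes -0.37, epithelial and tumour cell genes -0.69 and alternative activation -0.087 turned with equal medians in the ISAC against isotype ISAC. NF-kB and TLR signalling -0.16, dendritic cell -0.44, checkpoints 0.15, co-stimulation 0.065, inflammasome and cell death -0.36, endothelial and vascular genes -0.19, fibroblast and matrix genes -0.17 and epithelial and tumour cell genes -0.19 turned with quantile normalization in the ISAC against isotype ISAC. Inflammasome and cell death -0.32 and epithelial and tumour cell genes -0.32 turned with median-ratio scaling in the ISAC against isotype ISAC. Reference genes -0.074 turned with reference-list scaling in the ISAC against isotype ISAC. NF-kB and TLR signalling -0.098 and endothelial and vascular genes -0.018 turned with equal medians in anti-rHER2 against isotype antibody. NF-kB and TLR signalling -0.072 turned with quantile normalization in anti-rHER2 against isotype antibody. NF-kB and TLR signalling -0.23, dendritic cell -0.46, inflammasome and cell death -0.40, endothelial and vascular genes -0.34 and reference genes -0.46 turned with equal medians in the interaction. Inflammasome and cell death -0.20 and reference genes -0.25 turned with quantile normalization in the interaction.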

Other observations

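All list tests in this part were planned, and median-ratio scaling was chosen after the data were seen. Values with an estimated correlation are again those of camera, which sets a list against the other genes. In the anti-rHER2 ISAC against anti-rHER2, of the neutrophil genes 6 of 17 were higher and 0 lower (6 and 0 adjusted over the list alone), with a median of 0.28. The neutrophil list had a fry adjusted p of 0.00103 and adjusted p = 0.873 with an estimated correlation. Of the NF-kB and TLR genes, 9 of 29 were higher and 0 lower (9 and 0 adjusted over the list alone), with a median of 0.22, and the direction of the test turned with equal medians and quantile normalization. The NF-kB and TLR list had a fry adjusted p of 0.00171 and adjusted p = 0.873 with an estimated correlation. Of the cytotoxic and NK cell markers, 6 of 23 were higher and 1 lower (7 and 1 adjusted over the list alone), with a median of 0.34, and the direction of the test turned with equal medians. The cytotoxic and NK cell list had a fry adjusted p of 0.0273 and adjusted p = 0.873 with an estimated correlation. Of the MHC class I genes, 3 of 15 were higher and 0 lower (6 and 0 adjusted over the list alone), with a median of 0.53, and the direction of the test turned with equal medians. The MHC class I list had a fry adjusted p of 0.0273 and adjusted p = 0.873 with an estimated correlation. Against the isotype ISAC, of the T cell markers 6 of 19 were higher and 0 lower (0 and 0 adjusted over the list alone), with a median of 0.58, and the direction of the test turned with equal medians. The T cell list had a fry adjusted p of 0.0128 and adjusted p = 0.96 with an estimated correlation.

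In anti-rHER2 against the isotype antibody, of the fibroblast and matrix genes 3 of 13 were higher and 0 lower (4 and 0 adjusted over the list alone), with a median of 0.33. The fibroblast and matrix list had a fry adjusted p of 0.00499 and adjusted p = 0.939 with an estimated correlation. Of the endothelial genes, 1 of 17 was higher and 0 lower (1 and 0 adjusted over the list alone), with a median of 0.27, and the direction of the test turned with equal medians. The endothelial list had a fry adjusted p of 0.00948 and adjusted p = 0.957 with an estimated correlation. Of the inflammatory cytokine genes, 3 of 18 were higher and 0 lower (3 and 0 adjusted over the list alone), with a median of 0.20. The inflammatory cytokine list had a fry adjusted p of 0.00287 and adjusted p = 0.957 with an estimated correlation. Of the neutrophil genes, 3 of 17 were higher and 1 lower (5 and 1 adjusted over the list alone), with a median of 0.46. The neutrophil list had a fry adjusted p of 0.00948 and adjusted p = 0.957 with an estimated correlation. In this comparison the type I interferon list had 1 higher and 0 lower members of 28 (fry adjusted p = 0.222).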
